A study of Bos taurus with 5 samples.

How the data were processed

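Per the labels' protocols, discs were dissected from tails within 4 h of slaughter, quartered and held overnight at 4 °C. Mincing was followed by 0.2% pronase for 1 h and by collagenase I at 400 U/mL overnight, at 37 °C and 20% oxygen. Per the same protocols, 5000 cells were loaded per channel of the 10x Chromium 3′ v3 kit with 3000 targeted, reads came from a NovaSeq S1 flow cell at about 20000 per cell, and 14555 cells were stated in total. Per the file headers and the submitters' processing notes, the matrices came from Cell Ranger 5.0.0, and the notes also name Seurat without a version; the labels' protocols name Cell Ranger 3.1.0. The genome build and gene annotation are not given in the sources used here. Per the file headers, the deposited matrices hold whole UMI counts per gene and cell-containing barcode, and these raw counts were used without further change.

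Each of the 5 matrices held 21861 Ensembl identifiers, of which 4916 had no symbol, and 142 identifiers shared 68 symbols. The RefSeq gene table matched 0 identifiers, so the symbols in the files were used. Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% UMIs from the 13 mitochondrial genes, and with no doublet call. Scrublet, run per library in scanpy 1.11.5 with 0.8% doublets expected per 1000 cells, called 17 doublets (0.0951% of cells) and has not worked here, so a setting chosen after the data were seen removed the highest-scoring 556 (3.11%) instead.

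Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, ranked within library, were centred and scaled within library after the gene lists, mitochondrial genes and ribosomal genes had been left out. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9, seed 0). The 15 sets of cell type markers, from notochordal, cartilage-like and fibrous disc to endothelial, mural, muscle, myeloid, lymphoid, mast, erythroid, Schwann, adipocyte, hypertrophic, keratinocyte and proliferating cells, and the 20 gene lists were fixed before the data were examined. So were the cell filter, the tests, the named-gene rule and most alternative settings.

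Only classes with at least 3 markers detected in at least 10% of the cells of a cluster could name it. Among these it took the one with the highest mean marker score, defined as log2 of CPM plus 5 centred over clusters, from markers at 50 CPM or more in some cluster. The name needed a score of at least 0.8 and a lead of at least 0.5 over the next of these classes. Cluster 0 was so named mural-like at 3.98, although skeletal muscle scored 6.10 from 1 marker. A cluster with a median depth under 1/3 of its discs' median and no marker of its own among its 10 leading genes stayed unnamed. These thresholds were set after the data were seen. Of 17 clusters, 12 were named and 5 were not. Shares per disc carry exact (Clopper-Pearson) binomial 95% intervals, which hold counting error only; means and SD are over 3 animals, each animal being the mean of its discs.

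Raw counts were summed per animal and class where at least 20 cells were present, giving 15 sums. All classes were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the animal as a block. Genes were tested with the two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment over 13313 genes at 0.05. The 11546 of these genes not used for clustering are counted apart, because cells grouped by a gene's own values will differ in it. Log2 fold changes are edgeR model estimates. Their standard errors were worked back from the quasi-likelihood F and are not spreads over animals. SDs are over animals. The endothelial-like and mural-like classes were tested against the mean of the log values of the 3 disc classes.

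The lists held 729 genes, of which 706 were in the files and 659 were tested. They covered proteoglycans, elastic fibre genes, collagen processing, glycosaminoglycan synthesis, matrix proteases, protease inhibitors, glycolysis, hypoxia, oxidative phosphorylation, cytokines, stress response, TGF-beta and BMP, WNT with Hedgehog and Notch, IGF and FGF, pleiotrophin and midkine, axon guidance, complement and antigen presentation, osmotic and channel genes, progenitor-associated genes and the cell cycle. Below, proteoglycans is short for proteoglycans and matrix glycoproteins, and cytokine genes for cytokines and inflammatory mediators. The lists were tested with camera in limma 3.58.1 (two-sided, preset correlation 0.01), adjusted over lists and comparisons. The correlation was also estimated per list, and fry was run as a self-contained test. A gene with 0 counts in a group was given a bound from 3 counts over that group.

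Named genes had adjusted p under 0.05, the same direction in every animal with both classes, a symbol, no use in clustering, no place among the markers, and no mitochondrial or ribosomal origin. The 6 highest and 6 lowest log2 fold changes were taken, with up to 2 members per direction of at most 6 lists with the largest changed share. Genes named outside this rule were chosen after their values were seen, and are marked so. Values of 3 such genes are not reported here. For animal 6 against animal 8 the rule took 8 genes per direction that passed, and none did.

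Animals 6 and 8 were compared on sums per disc within cartilage-like cells. Likeness of discs was tested with an exact permutation over the 15 ways to split the 5 discs into sets of 2, 1 and 2 (one-sided). The disc without dead cell cleanup was described with exact Poisson intervals, for genes with at least 100 UMIs in its sum and that of its partner. Correlations are across genes, and genes are not independent replicates. Dixon's ratio of gap to range, critical at 0.71 for 5 discs, was computed for 14 measures per disc, and chance alone passes it in about 1 of 20 groups of values.

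The gene and list tests were tested on simulated data made from these sums. Simulated changes, those of the list below included, were placed only in genes above a floor on mean CPM. The recovery rates therefore do not cover genes of low counts. They rest on 67, 67 and 66 changed genes for the rising folds, in sums otherwise drawn from a shared profile. In the real sums 5394 of 13313 genes differed. Changed genes were recovered at 71.6, 98.5 and 100% for 2-, 4- and 8-fold changes between fibrous-like and cartilage-like sums, with 15 false calls among 12562 genes. Recovery with the 2 notochordal-like sums was 31.3, 83.6 and 98.5% against cartilage-like and 32.8, 85.1 and 97.0% against fibrous-like cells. For animal 6 against animal 8 it was 22.4, 100 and 100%, in simulated counts that varied only by each gene's fitted dispersion. On the real sums the same test called 0 of 12909 genes and left out ULBP21 at 56.3-fold (edgeR adjusted p = 0.0583). This recovery therefore does not show that real 4-fold differences between these animals would be called. Between fibrous-like and cartilage-like sums a simulated list of 30 genes at 2-fold gave a limma camera adjusted p = 3.61e-98. With an estimated correlation its limma camera adjusted p = 1.03e-06, and 0 of the other lists were called either way. These counts too varied only by each gene's fitted dispersion, so the simulated genes of a list did not vary together. The list test therefore cannot show whether the preset correlation is adequate for real lists, whose genes may vary together.

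Alternatives fixed beforehand were no replicate block, sums per disc, DESeq2 1.42.0, RLE size factors, no count filter, each animal or disc left out, an added log2 fold change of 1, stricter and looser cell filters, doublets kept, Leiden at 0.4 and 1.2, centring over all cells, sums thinned to the same total, Spearman correlation and sums over all cells. Settings chosen after the data were seen removed the highest doublet scores, left out the cluster led by immediate early genes, added clusters 2 and 7 to the cartilage-like class, placed animal 8 disc 2 with animal 7, set endothelial-like and mural-like cells against cartilage-like and fibrous-like cells only, or kept each barcode only in the library where it had the most UMIs. Lists were retested only without the block, with each animal left out, and without the cluster led by immediate early genes. Further list settings placed animal 8 disc 2 with animal 7, kept each barcode only in its main library, or used the cartilage-like and fibrous-like contrast. Ranges of camera adjusted p over the alternatives cover these settings alone. Other software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, numba 0.67.0 and matplotlib 3.10.9. Raw reads and barcodes outside the filtered matrices were not analysed here, so free RNA was not removed.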

Results

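Single-cell RNA libraries from 5 caudal intervertebral discs of 3 cattle were examined: discs 3 and 4 of animal 6, disc 3 of animal 7, and discs 1 and 2 of animal 8. Only animal 8 disc 2 was labelled as prepared without dead cell cleanup. The matrices held 34429074, 53075040, 38113497, 40783087 and 19310677 UMIs in that order, over 21861 genes. They held 6054, 7021, 4217, 5622 and 2609 barcodes, 25523 in all, beside the 14555 cells stated in the labels. The animal, not the cell, was the replicate.

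A filter of at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs left 17873 barcodes. Low genes or UMIs removed 7590 and mitochondrial content 140, with barcodes that failed both rules counted in each number. Passing barcodes made up 67.8, 73.9, 72.0, 71.9 and 57.4% per disc, the last being the disc without cleanup (exact Clopper-Pearson binomial 95% interval 55.5 to 59.3%). After 17 doublet calls 4105, 5183, 3034, 4040 and 1494 cells were kept, 17856 in all. The doublet caller marked under 0.5% of cells and has not worked here. Median UMIs per kept cell were 7991, 9817, 12057, 10384 and 11698.5, and median genes 2000, 2353, 2596.5, 2522 and 2645.5.

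Many barcode sequences occurred in more than 1 library. Of 16682 different sequences, 3145 occurred in 2 or more libraries and 1307 in all 5. Counting each sequence only in the library where it had the most UMIs, 8841 of the 25523 barcodes were repeats. Their median was 727 UMIs, against 10252 over all barcodes that were not repeats, most of which occurred in 1 library only. The filter removed most of them, but 2155 of the 17856 kept cells (12.1%) were repeats, from 3.95% in animal 8 disc 2 to 19.1% in animal 8 disc 1. Without them 15701 cells were left, while a stricter filter of at least 1000 genes and at most 10% mitochondrial UMIs left 14689. Which step gave the stated 14555 was not worked out. The results below include the repeats unless stated. Without repeats the mean shares of the classes named below were 49.3% cartilage-like, 21.5% fibrous-like and 10.6% endothelial-like. With repeats they were 44.7, 19.8 and 9.71%. Between fibrous-like and cartilage-like cells 5360 genes differed without repeats and 5394 with them.

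Cartilage-like cells, with COL2A1 at 23980 ± 5150 CPM and ACAN at 2774 CPM (mean and SD, n = 3 animals), made up 44.7 ± 9.85% of cells (7625 cells). Fibrous-like cells, led by COL1A1, COL1A2, SFRP2, MFAP5, CD248 and FOS, made up 19.8 ± 9.12% (3645 cells). COL1A1 in this class was 5826 ± 8677 CPM, a spread set by animal 8. Endothelial-like cells (9.71 ± 1.61%, 1843 cells) held PECAM1 at 604 ± 38.5 CPM and CDH5 at 703 ± 11.3 CPM, and mural-like cells (5.49 ± 2.24%, 1179 cells) held ACTA2 at 442 ± 156 CPM and MYH11 at 283 ± 78.2 CPM. Schwann-like cells (0.158 ± 0.183%, 39 cells) held SOX10, and 0 of 3034 cells were found in animal 7, with an exact upper limit of 0.122%. COL2A1 at 903 CPM in endothelial-like and 873 CPM in mural-like cells may not be their own, and its source was not tested.

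Notochordal-like cells were rare, at 0.671 ± 0.580% (106 cells: 58, 39 and 9 in animals 6, 7 and 8). They held KRT8 at 1692 ± 77.1 CPM, SHH at 159 ± 0.869 CPM and TBXT at 76.8 ± 19.8 CPM (n = 2 animals), genes that mark notochord-derived cells of the nucleus pulposus, against 0.826 CPM of KRT8 in cartilage-like cells. All 9 in animal 8 were repeats of barcodes with more UMIs in the disc of animal 7, so that 56, 39 and 0 remained. Their median depth was 1056 UMIs, against 18194.5 in animal 6 and 20536 in animal 7. No notochordal-like cell class was found when values were centred over all cells.

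Disc 1 of animal 8 differed most in its makeup, with 21.5% cartilage-like cells (95% interval 20.2 to 22.8%) and 36.0% fibrous-like cells (34.5 to 37.5%). The other discs held 45.6 to 52.0% cartilage-like and 11.1 to 24.6% fibrous-like cells. Its fibrous-like class was 65.6% COL1A1-high cells of cluster 3. In the other discs cluster 9, led by SNAI1, HSPA6, EGR1, FOSB and FOS, held 48.0 to 73.9% of the class, against 25.3% in that disc. Within the cartilage-like class, cluster 5 (PCDH8, FRZB, CHRDL2) held 51.9 and 56.8% in animal 6. Cluster 8 was led by the chaperone and stress genes SDF2L1, HERPUD1, DNAJB11 and HSPA5. It held 46.5, 39.6 and 57.1% in animal 7 and in discs 1 and 2 of animal 8. Cluster 4 (S100A2, CSPG4, HAPLN1) and cluster 6 (HP, CRISPLD1, MMP3, CHI3L1) completed the class.

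Unnamed cells made up 19.5 ± 2.42%, or 12.1% once repeats were removed. Cluster 7 (1727 cells, median 1379 UMIs) consisted of repeats to 89.5%. Cluster 2 (1288 cells; WDR73, PRG4, SAA3, HP, SOD2) was kept out by a score threshold set after the data were seen and held 6.60, 5.50, 12.5, 3.94 and 12.9% of the 5 discs. Cluster 13 (110 cells; SRGN, TYROBP, FCER1G, IL7R) mixed myeloid, mast and lymphoid markers (scores of 5.10, 4.85 and 4.68) and held 0.317, 0.347, 0.297, 1.63 and 0.268%. The stricter filter split such cells into a myeloid-like cluster of 37 cells (score 5.38) and a mast-like cluster of 48 cells (6.07). Clusters 15 and 16 were shallow.

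**Figure D1:**
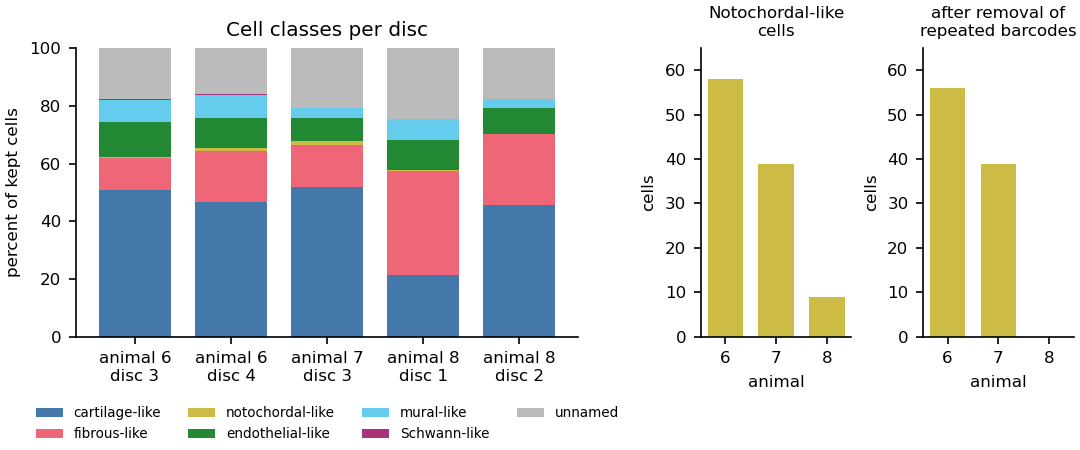
Share of each cell class in each disc, and notochordal-like cells per animal before and after repeated barcodes were removed.

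**Figure D2:**
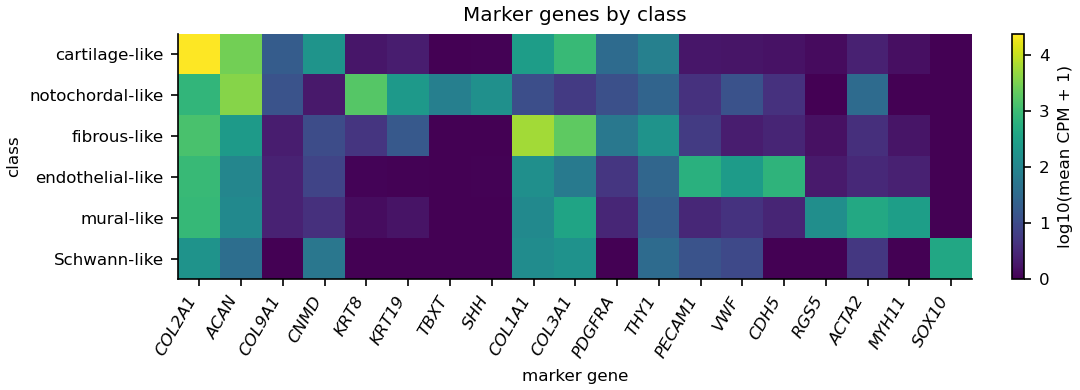
Mean CPM (log10) of marker genes in each cell class.

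In fibrous-like against cartilage-like cells CFD, the complement protease factor D, was higher by a log2 fold change of 8.45 ± 0.575 (model estimate ± SE, edgeR adjusted p = 5.68e-07). Its level was 54.9 ± 26.6 against 0.132 ± 0.106 CPM (mean ± SD, n = 3 animals). MFAP5 rose by 7.66 ± 0.50 (169 against 0.834 CPM), SFRP2 by 7.50 ± 0.719, A2M by 7.35 ± 1.05 and IGF1 by 7.29 ± 0.537 (9.09 against 0.0418 CPM). EYA4, with 0 counts in cartilage-like cells, was at least 75.8-fold higher. In the other direction HSPA5 was −3.19 ± 0.318 (2155 ± 650 against 19451 ± 8474 CPM; edgeR adjusted p = 6.39e-06), SERPINA1 −4.99 ± 0.706 (230 against 3732 CPM), S100A1 −3.36 ± 0.449 (254 against 1646 CPM) and SNCB −6.22 ± 0.524. KLC3, DENND2D, OXTR, OLIG1 and NTF4 had 0 counts in fibrous-like cells and were at least 14.4-, 18.2-, 9.75-, 11.7- and 12.3-fold lower, from under 2 CPM in cartilage-like cells.

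In all, 5394 of 13313 genes differed (2677 higher, 2717 lower in fibrous-like cells; 2563 and 2281 with DESeq2, 2753 and 2612 with RLE, 2643 and 2936 without a count filter), 4365 of them among the 11546 genes not used for clustering. The calls of EYA4, KLC3 and OLIG1 were lost with DESeq2, that of OXTR without animal 8, and that of NTF4 without animal 6. Without animal 8 the count was 3407, within a range of 3407 to 5029 over animals and discs left out. With sums thinned to the same total it was 2447 of 8590 tested genes (2343 shared with the full sums), where the calls of NTF4, ADAM15 and SOX6 were lost, and with a log2 fold change of at least 1 it was 3219 (1697 higher, 1522 lower). Without cluster 9 5048 genes differed (4035 shared), and with a log2 fold change of at least 1 the balance turned to 1244 higher and 1816 lower. With animal 8 disc 2 summed with animal 7 it was 1602 and 1612.

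Of 46 stress-response genes, 35 rose and 1 fell in fibrous-like cells (36 and 1 adjusted over the list alone), with a median log2 fold change of 2.10 (limma camera adjusted p = 4.45e-17, adjusted p = 0.164 with an estimated correlation). ZFP36L1 was 5.35 ± 0.243 (2267 ± 421 against 56.7 ± 18.3 CPM) and HSPH1 2.57 ± 0.159. The list median fell to 0.24 when cluster 9 was left out (15 rose and 5 fell, limma camera adjusted p = 0.0483, the highest of 1.98e-19 to 0.0483 over the alternatives at the preset correlation). Of 52 genes of cytokines and inflammatory mediators 34 rose and 5 fell (37 and 5 adjusted over the list alone). The list median was 1.69, or 1.05 without cluster 9 (limma camera adjusted p = 1.65e-08, adjusted p = 0.0943 with an estimated correlation). CSF1 was 4.95 ± 0.350 and TNFAIP3 3.27 ± 0.255, while MIF was −1.33 ± 0.197.

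Elastic fibre genes rose in 11 of 18 and fell in 1 (11 and 1 adjusted over the list alone), with a median of 1.02 (limma camera adjusted p = 0.000266, adjusted p = 0.0943 with an estimated correlation). FBLN1 (6.40 ± 0.490) and FBLN5 (5.12 ± 0.339) are examples chosen after their values were seen, as is C1S below. Matrix proteases rose in 21 of 38 and fell in 7 (21 and 7 adjusted over the list alone), with a median of 1.17 (limma camera adjusted p = 2.76e-05, adjusted p = 0.137 with an estimated correlation). ADAMTS4, an aggrecanase, was 5.41 ± 0.285 (45.5 against 1.08 CPM) and CTSS 3.46 ± 0.219, while MMP17 was −2.92 ± 0.427 and ADAM15 −1.03 ± 0.160. Among 19 protease inhibitors 8 rose and 6 fell (8 and 6 adjusted over the list alone), with TFPI2 at 3.96 ± 0.243, SERPING1 at 3.15 ± 0.194 and SPINT2 at −2.37 ± 0.25, and the list did not pass (limma camera adjusted p = 0.286, adjusted p = 0.491 with an estimated correlation). Complement and antigen presentation genes rose in 16 of 34 and fell in 3 (17 and 3 adjusted over the list alone), with C1S at 3.63 ± 0.238 and a median of 1.34 (limma camera adjusted p = 0.000116, adjusted p = 0.164 with an estimated correlation).

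IGF and FGF genes rose in 15 of 29 and fell in 6 (16 and 6 adjusted over the list alone), with a median of 1.67, or 1.01 without cluster 9 (limma camera adjusted p = 0.00106, adjusted p = 0.215 with an estimated correlation). IGFBP4 was 5.32 ± 0.323 and FGF10 5.33 ± 0.397, against FGFR3 at −2.10 ± 0.326 and FGFR4 at −3.07 ± 0.445. Progenitor-associated genes rose in 10 of 18 and fell in 3 (11 and 3 adjusted over the list alone), with a median of 1.2 (limma camera adjusted p = 0.000495, adjusted p = 0.0943 with an estimated correlation). CD44 was 5.23 ± 0.421 and CTSK 3.56 ± 0.271, while the cartilage regulators SOX5 and SOX6 were −1.40 ± 0.309 and −2.18 ± 0.403.

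Smaller shifts depended on single choices. TGF-beta and BMP genes rose in 23 of 47 and fell in 8 (25 and 9 adjusted over the list alone, median 0.57, limma camera adjusted p = 0.00364, adjusted p = 0.245 with an estimated correlation). Oxidative phosphorylation genes fell in 21 of 68 and rose in 3 (20 and 3 adjusted over the list alone, median −0.27, limma camera adjusted p = 0.000748, adjusted p = 0.443 with an estimated correlation). The median mitochondrial share went the other way, at 1.03, 0.896 and 1.61% in fibrous-like against 0.663, 0.626 and 0.605% in cartilage-like cells of animals 6, 7 and 8. Both list calls ended without cluster 9, at the top of limma camera ranges over the alternatives of 0.00108 to 0.131 and 0.000417 to 0.155. WNT, Hedgehog and Notch genes (18 rose, 9 fell of 48; 20 and 9 adjusted over the list alone, median 0.51, limma camera adjusted p = 0.0104, adjusted p = 0.359 with an estimated correlation) and cell cycle genes (12 rose, 3 fell of 26; 12 and 4 adjusted over the list alone, median 0.43, limma camera adjusted p = 0.0241, adjusted p = 0.368 with an estimated correlation) lost their calls without animal 7, without cluster 9, or with animal 8 disc 2 placed with animal 7. Glycosaminoglycan synthesis fell in 13 of 35 genes and rose in 3 (13 and 5 adjusted over the list alone, median −0.51, limma camera adjusted p = 0.0369, adjusted p = 0.415 with an estimated correlation). That call ended without the block, without animal 6 or 8, and without cluster 9 (limma camera adjusted p from 0.0301 to 0.152 over the alternatives). Genes of proteoglycans and matrix glycoproteins split, with 14 rising and 12 falling of 37 (14 and 12 adjusted over the list alone). The median was −0.01 while the mean was 0.79, and camera in limma read the list as higher (adjusted p = 0.0421, adjusted p = 0.359 with an estimated correlation). This call ended in 6 alternatives, among them the removal of repeats.

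Collagen processing (3 rose, 11 fell of 27), glycolysis (6 and 7 of 25), hypoxia (8 and 7 of 23), pleiotrophin and midkine (4 and 2 of 15), axon guidance (9 and 6 of 32) and osmotic genes (6 and 2 of 24) did not pass as lists, with limma camera adjusted p from 0.109 to 0.99. Cartilage-like markers fell in 11 of 14 (median −3.38, adjusted p = 0.405 with an estimated correlation) and fibrous markers rose in 9 of 15 (median 1.48, adjusted p = 0.0959 with an estimated correlation). These sets named the classes, so their direction was fixed beforehand. Keratinocyte markers fell in 4 of 5 (median −3.04, adjusted p = 0.342 with an estimated correlation). The other marker sets did not pass: endothelial (5 rose, 2 fell of 13), mural (7 and 1 of 12), myeloid (4 and 1 of 7), Schwann (2 and 1 of 10), hypertrophic (3 and 3 of 6), notochordal (2 and 3 of 13), proliferating (1 and 2 of 7), lymphoid (0 and 0 of 4), mast (0 and 1 of 3), erythroid (0 and 1 of 4) and muscle (0 and 1 of 6). Too few adipocyte markers were measured to test.

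**Figure D3:**
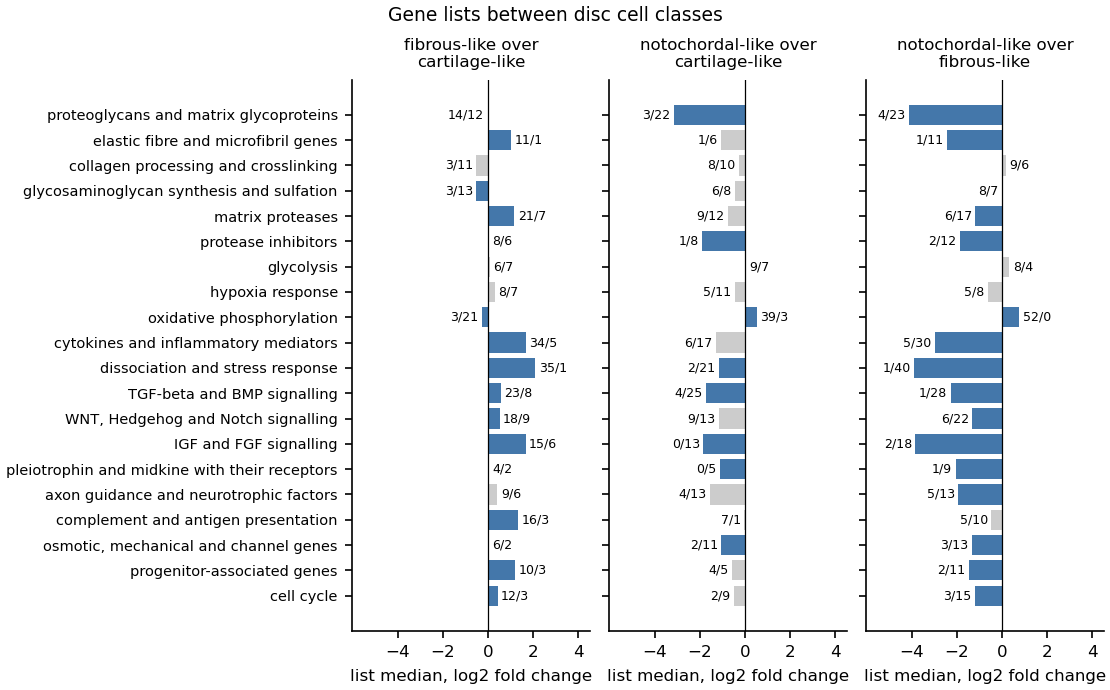
Median log2 fold change of each gene list per comparison, with genes at 0 counts in a class set at their bound and the numbers that rose and fell. Lists with limma camera adjusted p under 0.05 are blue.

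DCN and BGN, which encode small proteoglycans, were lower in notochordal-like than in cartilage-like cells. DCN had a log2 fold change of −8.16 ± 0.378 (24.6 ± 14.3 against 5958 ± 3370 CPM; n = 2 animals; edgeR adjusted p = 1.66e-08) and BGN −6.97 ± 0.517 (32.9 against 4293 CPM). LPAR1, EDIL3, HHIPL2, KCNK17, NTRK2 and SEMA3D had 0 counts in notochordal-like cells and were at least 91.6-, 57.8-, 37.1-, 35.3-, 34.1- and 30.2-fold lower. TMEM163 rose by 9.90 ± 0.467 (137 ± 13.3 against 0.139 CPM). C22H3orf49, TNFSF18, SALL1 and CTNNA2, absent from cartilage-like counts, were at least 1412-, 694-, 257- and 238-fold higher, and CD96, with 2 counts in cartilage-like cells, was 1805-fold higher (exact Poisson 95% interval 489 to 15069).

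Between these classes 5049 of 13313 genes differed (2370 higher, 2679 lower in notochordal-like cells; 2539 and 2203 with DESeq2, 2649 and 2394 with RLE, 1924 and 3132 without a count filter), 4298 of them among genes not used for clustering. Only animals 6 and 7 had 20 notochordal-like cells. Without animal 6 the count was 2532, without animal 7 3117 and without animal 6 disc 4 2826, within a range of 2532 to 5022; each leaves 1 notochordal-like sum, which is assumed to vary like the other groups. The call of SALL1 was lost with DESeq2, those of PLOD2 and FSTL1 without animal 7, and those of ALDOC and COX4I1 without animal 6. With sums thinned to the same total 3225 of 8590 tested genes differed (3052 shared with the full sums), and the call of ACVR2B was lost. The median of all genes was −0.13 with TMM, 0.03 with DESeq2, −0.04 with RLE and −0.51 without a count filter, so shifts below about 0.5 depend on scaling and filter.

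Oxidative phosphorylation rose in 39 of 68 genes and fell in 3 (42 and 4 adjusted over the list alone), with NDUFA11 at 1.36 ± 0.166, ATP5F1D at 1.26 ± 0.178, UQCRH at −0.91 ± 0.177 and COX4I1 at −0.62 ± 0.154. The list median was 0.53 (limma camera adjusted p = 5.13e-07, adjusted p = 0.292 with an estimated correlation). The median mitochondrial share of notochordal-like cells was higher too, at 3.75 and 3.71% against 0.663 and 0.626% in animals 6 and 7. Glycolysis was mixed, with 9 of 25 rising and 7 falling (9 and 7 adjusted over the list alone), and did not pass (limma camera adjusted p = 0.217, adjusted p = 0.679 with an estimated correlation). LDHA (2.09 ± 0.230; 326 against 75.1 CPM) and PGAM1 (2.07 ± 0.192) rose, and PFKFB4 (−3.19 ± 0.464) and ALDOC (−1.64 ± 0.356) fell. HIF1A was 1.39 ± 0.221 (459 against 151 CPM) and BHLHE41 1.51 ± 0.228, while BNIP3L and P4HA1 were −1.36 ± 0.187 and −1.68 ± 0.270; of 23 hypoxia genes 5 rose and 11 fell (5 and 11 adjusted over the list alone, limma camera adjusted p = 0.286, adjusted p = 0.679 with an estimated correlation).

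Genes of proteoglycans and matrix glycoproteins fell in 22 of 37 and rose in 3 (24 and 3 adjusted over the list alone). Among the 3 were the glycoprotein genes TNXB at 5.41 ± 0.268 and NID2 at 2.01 ± 0.242. The list median was −3.90, or −3.14 with genes at 0 counts set at their bound (limma camera adjusted p = 4.41e-08, adjusted p = 0.0943 with an estimated correlation). Stress-response genes fell in 21 of 46 and rose in 2 (25 and 2 adjusted over the list alone, median −1.15, limma camera adjusted p = 8.98e-06, adjusted p = 0.415 with an estimated correlation). TGF-beta and BMP genes fell in 25 of 47 and rose in 4 (29 and 4 adjusted over the list alone, median −1.76, at bounds −1.71, limma camera adjusted p = 9.47e-05, adjusted p = 0.164 with an estimated correlation), with BMP2 at −3.18 ± 0.314, ACVR1 at −2.54 ± 0.254, ACVR2B at 3.24 ± 0.450 and FSTL1 at 1.13 ± 0.258. IGF and FGF genes fell in 13 of 29 and rose in 0 (14 and 0 adjusted over the list alone, median −2.42, at bounds −1.84, limma camera adjusted p = 0.000409, adjusted p = 0.255 with an estimated correlation).

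Osmotic and channel genes fell in 11 of 24 and rose in 2 (15 and 3 adjusted over the list alone, median −1.14, at bounds −1.05, limma camera adjusted p = 0.00268, adjusted p = 0.200 with an estimated correlation). Protease inhibitors fell in 8 of 19 and rose in 1 (9 and 1 adjusted over the list alone, median −1.90, limma camera adjusted p = 0.00404, adjusted p = 0.215 with an estimated correlation). Pleiotrophin and midkine genes fell in 5 of 15 and rose in 0 (5 and 0 adjusted over the list alone, median −1.14, at bounds −1.11, limma camera adjusted p = 0.0384, adjusted p = 0.415 with an estimated correlation), a call that ended without animal 6, without cluster 9, and with animal 8 disc 2 placed with animal 7 (adjusted p from 0.0236 to 0.260 over the alternatives). Among collagen processing genes, PLOD1 was 1.78 ± 0.251 and PLOD2 1.02 ± 0.240, against PCOLCE at −4.26 ± 0.304 and PCOLCE2 at −4.29 ± 0.352; 8 of 27 rose and 10 fell (8 and 10 adjusted over the list alone), and the list did not pass (limma camera adjusted p = 0.217, adjusted p = 0.520 with an estimated correlation). Elastic fibre, glycosaminoglycan, protease, cytokine, WNT, axon, complement, progenitor and cell cycle lists did not pass either, with limma camera adjusted p from 0.0702 to 0.635. Notochordal markers rose in 7 of 13 (median 5.14), endothelial in 6 of 13 (2.33) and Schwann in 5 of 10 (1.28), while cartilage-like markers fell in 10 of 14 and fibrous markers in 8 of 15. The notochordal and cartilage-like sets named these classes. Their adjusted p = 0.405, 0.414, 0.114, 0.414 and 0.405 with an estimated correlation.

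In notochordal-like against fibrous-like cells HSPA1A had a log2 fold change of −4.79 ± 0.291 (232 ± 5.19 against 6362 ± 755 CPM; n = 2 animals; edgeR adjusted p = 1.95e-07) and DNAJB1 −4.25 ± 0.235. FGF7, MFAP5, MMP2, IGFBP4, LPAR1 and EDIL3 had 0 counts in notochordal-like cells and were at least 385-, 161-, 121-, 82.0-, 40.2- and 31.2-fold lower. C22H3orf49, SLC2A5, PAX2, CHRM2, ADCYAP1, TRIM6 and SPOCK1, with 0 counts in fibrous-like cells, were at least 297-, 147-, 106-, 102-, 95.9-, 53.2- and 40.4-fold higher. TWIST1, with 2 counts in notochordal-like cells, was 367-fold lower (exact Poisson 95% interval 102 to 3033).

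Here 5322 of 13313 genes differed (2616 higher, 2706 lower in notochordal-like cells; 2638 and 2333 with DESeq2, 2818 and 2442 with RLE, 2175 and 3024 without a count filter), 4470 of them among genes not used for clustering. Without animal 6 the count was 2882, without animal 7 3225 and without animal 6 disc 4 3104, within a range of 2882 to 5159; the lone notochordal-like sum is again assumed to vary like the other groups. DESeq2 did not call ADCYAP1, SLC2A5, C22H3orf49 and SPOCK1, and HSPE1, TIMP3, ALCAM and CDKN2C were lost without animal 7. The median of all genes was −0.09 with TMM, 0.02 with DESeq2 and −0.40 without a count filter.

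Stress-response genes fell in 40 of 46 and rose in 1, HSPE1 at 0.83 ± 0.180 (40 and 1 adjusted over the list alone). The median was −3.96, at bounds −3.89 and without cluster 9 −1.84 (limma camera adjusted p = 2.40e-23, adjusted p = 0.164 with an estimated correlation). Oxidative phosphorylation rose in 52 of 68 and fell in 0 (54 and 0 adjusted over the list alone), with NDUFA7 at 1.64 ± 0.150, NDUFA8 at 1.67 ± 0.173 and a median of 0.76 (limma camera adjusted p = 6.67e-14, adjusted p = 0.164 with an estimated correlation). The median mitochondrial share of fibrous-like cells was 1.03 and 0.896% in animals 6 and 7, below that of notochordal-like cells. Genes of proteoglycans and matrix glycoproteins fell in 23 of 37 and rose in 4 (26 and 4 adjusted over the list alone). They ran from DCN at −8.42 ± 0.380 and CCN3 at −6.21 ± 0.465 to VCAN at 2.12 ± 0.360 and HSPG2 at 2.67 ± 0.439. The list median was −4.46, at bounds −4.10 (limma camera adjusted p = 2.94e-11, adjusted p = 0.0943 with an estimated correlation). TGF-beta and BMP genes fell in 28 of 47 and rose in 1 (29 and 1 adjusted over the list alone, median −2.30, at bounds −2.27, limma camera adjusted p = 5.17e-09, adjusted p = 0.0943 with an estimated correlation). Cytokine genes fell in 30 of 52 and rose in 5 (30 and 5 adjusted over the list alone, median −3.57, at bounds −2.99, limma camera adjusted p = 4.04e-07, adjusted p = 0.0943 with an estimated correlation).

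IGF and FGF genes fell in 18 of 29 and rose in 2 (18 and 2 adjusted over the list alone, median −3.86, at bounds −3.84, limma camera adjusted p = 4.17e-07, adjusted p = 0.164 with an estimated correlation). Elastic fibre genes fell in 11 of 18 and rose in 1 (12 and 1 adjusted over the list alone, median −2.43, limma camera adjusted p = 2.28e-05, adjusted p = 0.0943 with an estimated correlation). Protease inhibitors fell in 12 of 19 and rose in 2 (13 and 2 adjusted over the list alone, median −2.07, at bounds −1.86, limma camera adjusted p = 0.000273, adjusted p = 0.137 with an estimated correlation), with TFPI2 at −6.0 ± 0.351 and TIMP3 at 1.37 ± 0.307. Progenitor-associated genes fell in 11 of 18 and rose in 2 (11 and 3 adjusted over the list alone, median −2.39, at bounds −1.47, limma camera adjusted p = 0.00113, adjusted p = 0.164 with an estimated correlation), with CTSK at −4.08 ± 0.350 and SOX6 at 3.87 ± 0.469. Matrix proteases fell in 17 of 38 and rose in 6 (18 and 6 adjusted over the list alone, median −2.30, at bounds −1.18, limma camera adjusted p = 0.00142, adjusted p = 0.246 with an estimated correlation).

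Osmotic genes fell in 13 of 24 and rose in 3 (15 and 4 adjusted over the list alone, median −1.48, at bounds −1.32, limma camera adjusted p = 0.00107, adjusted p = 0.164 with an estimated correlation). Pleiotrophin and midkine genes fell in 9 of 15 and rose in 1 (9 and 1 adjusted over the list alone, median −2.61, at bounds −2.06, limma camera adjusted p = 0.00420, adjusted p = 0.246 with an estimated correlation). Cell cycle genes fell in 15 of 26 and rose in 3 (15 and 3 adjusted over the list alone, median −1.19, limma camera adjusted p = 0.00388, adjusted p = 0.294 with an estimated correlation); the inhibitors CDKN1C and CDKN1A were −6.06 ± 0.689 and −4.17 ± 0.465 and RRM1 was 1.40 ± 0.268. Axon guidance genes fell in 13 of 32 and rose in 5 (13 and 5 adjusted over the list alone, median −2.13, at bounds −1.93, limma camera adjusted p = 0.0149, adjusted p = 0.268 with an estimated correlation). These 2 calls ended without cluster 9, at the top of limma camera ranges over the alternatives of 0.00203 to 0.191 and 0.0136 to 0.0860. WNT, Hedgehog and Notch genes fell in 22 of 48 and rose in 6 (22 and 6 adjusted over the list alone, median −1.62, at bounds −1.31, limma camera adjusted p = 0.0384, adjusted p = 0.492 with an estimated correlation), a call that ended without the block, without animal 6 or cluster 9, and with animal 8 disc 2 placed with animal 7 (adjusted p from 0.0301 to 0.507 over the alternatives). Collagen processing (9 rose, 6 fell of 27; median 0.18 but mean −0.55), glycosaminoglycan synthesis (8 and 7 of 35; median −0.02, camera higher), glycolysis, hypoxia and complement did not pass (limma camera adjusted p from 0.223 to 0.940). Notochordal markers rose in 7 of 13 (median 4.37), endothelial in 4 of 13 (1.87) and Schwann in 4 of 10 (0.48), while fibrous markers fell in 14 of 15 (median −5.87, at bounds −4.52). The notochordal and fibrous sets named these classes. Their adjusted p = 0.342, 0.649, 0.300 and 0.0959 with an estimated correlation. Across the 3 comparisons camera called 36 of 60 lists, and with an estimated correlation 0 of 60.

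Among genes that set endothelial-like cells apart, examples chosen after their values were seen were BOLA-DRA, a class II gene, with a log2 fold change of 9.05 ± 0.249 over the disc classes (133 ± 13.5 against 0.249 ± 0.134 CPM; n = 3 animals; edgeR adjusted p = 4.42e-11), B2M at 3.69 ± 0.135 (6572 against 525 CPM) and the chemokine gene CXCL16 at 5.38 ± 0.25 (1097 against 28.7 CPM). PLOD2 was −3.57 ± 0.227 (12.6 against 145 CPM) and P3H3 −4.0 ± 0.288, both chosen in the same way. Cluster 11, 311 of the 1843 cells, was led by CXCL3, TNFAIP3, GRO1, CD83, CD74 and SELP. Its 10 leading genes held 0 endothelial markers and 1 myeloid marker, CD74, so its name rests on a mean endothelial score of 3.92. Of 13313 genes 6795 differed (3523 higher, 3272 lower), with a range of 4670 to 6494 over animals and discs left out. With sums thinned to the same total 3996 of 8590 differed, and with a log2 fold change of at least 1 4206. The balance turned with DESeq2 (3099 higher, 3545 lower) and RLE scaling (3248 and 3503).

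Complement and antigen presentation rose in 21 of 34 genes and fell in 4 (21 and 4 adjusted over the list alone, median 2.49, limma camera adjusted p = 3.02e-06, adjusted p = 0.287 with an estimated correlation). Collagen processing fell in 21 of 27 and rose in 1 (21 and 1 adjusted over the list alone, median −1.99, limma camera adjusted p = 1.02e-07, adjusted p = 0.261 with an estimated correlation). Cytokine genes rose in 27 of 52 and fell in 12 (27 and 14 adjusted over the list alone, median 1.41, limma camera adjusted p = 0.00278, adjusted p = 0.459 with an estimated correlation). Oxidative phosphorylation fell in 37 of 68 and rose in 2 (37 and 2 adjusted over the list alone, median −0.42, limma camera adjusted p = 2.21e-05, adjusted p = 0.494 with an estimated correlation) and glycolysis fell in 15 of 25 and rose in 3 (15 and 3 adjusted over the list alone, median −0.93, limma camera adjusted p = 0.0111, adjusted p = 0.598 with an estimated correlation). Glycosaminoglycan synthesis fell in 23 of 35 and rose in 6 (25 and 6 adjusted over the list alone, median −0.82, limma camera adjusted p = 0.000841, adjusted p = 0.459 with an estimated correlation), proteoglycans fell in 21 of 37 and rose in 7 (21 and 7 adjusted over the list alone, median −1.57, limma camera adjusted p = 0.00642, adjusted p = 0.459 with an estimated correlation) and elastic fibre genes fell in 11 of 18 and rose in 3 (11 and 3 adjusted over the list alone, median −1.96, limma camera adjusted p = 0.0116, adjusted p = 0.459 with an estimated correlation). The elastic fibre call ended without the block (limma camera adjusted p from 0.000835 to 0.0606 over the alternatives).

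Stress-response genes rose in 26 of 46 and fell in 6 (26 and 6 adjusted over the list alone, median 0.87, limma camera adjusted p = 0.00189, adjusted p = 0.667 with an estimated correlation). The main contrast averages log values over 3 disc classes. JUN, chosen after its values were seen, was 1.71 ± 0.272, yet 2531 against 2461 CPM on average. Against cartilage-like and fibrous-like cells only, a setting chosen after the data were seen, 7137 genes differed (5623 shared) and the stress list had a median of −0.21 (11 rose and 13 fell, 11 and 13 adjusted over the list alone). It did not pass (limma camera adjusted p = 0.999, adjusted p = 1.00 with an estimated correlation). The calls of cytokines, oxidative phosphorylation and glycolysis ended there too, while those of complement, collagen processing, glycosaminoglycan synthesis, proteoglycans and elastic fibre genes did not. Over the alternatives limma camera adjusted p ran from 2.65e-07 to 0.999 for stress, 0.00116 to 0.0743 for cytokines, 2.65e-07 to 0.104 for oxidative phosphorylation and 0.00874 to 0.0727 for glycolysis. Protease inhibitors did not pass and had a median of −0.94 but a mean of 0.07, and TGF-beta and BMP genes had a median of −0.08 while camera read them as higher. Endothelial markers rose in 13 of 13 (median 7.41) and mast markers in 2 of 3, while notochordal markers fell in 9 of 13, cartilage-like in 9 of 14, fibrous in 10 of 15 and keratinocyte in 4 of 5. The adjusted p = 0.125 with an estimated correlation for endothelial markers, which named the class, and 0.427 for the others.

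In mural-like cells NES had a log2 fold change of 3.98 ± 0.197 (77.0 ± 17.5 against 5.84 ± 1.49 CPM; n = 3 animals; edgeR adjusted p = 6.82e-09) and CXCL16 2.43 ± 0.25, while FKBP10 was −3.05 ± 0.266 and PLOD2 −1.89 ± 0.203, all chosen after their values were seen. In this class 5073 of 13313 genes differed (2443 higher, 2630 lower, but 2571 and 2406 without a count filter), with a range of 2957 (without animal 6) to 4848 over animals and discs left out. With sums thinned to the same total 3028 of 8590 differed, and with a log2 fold change of at least 1 2980. Collagen processing fell in 18 of 27 and rose in 2 (18 and 2 adjusted over the list alone, median −1.42, limma camera adjusted p = 3.02e-06, adjusted p = 0.287 with an estimated correlation). Progenitor-associated genes rose in 11 of 18 and fell in 4 (11 and 4 adjusted over the list alone, median 1.36, limma camera adjusted p = 0.00642, adjusted p = 0.459 with an estimated correlation), and IGF and FGF genes in 13 of 29, with 4 falling (14 and 4 adjusted over the list alone, median 1.06, limma camera adjusted p = 0.0123, adjusted p = 0.494 with an estimated correlation). Glycosaminoglycan synthesis fell in 16 of 35 and rose in 2 (18 and 2 adjusted over the list alone, median −0.61, limma camera adjusted p = 0.000841, adjusted p = 0.459 with an estimated correlation). Proteoglycans fell in 23 of 37 and rose in 5 (23 and 6 adjusted over the list alone, median −1.52, limma camera adjusted p = 0.00641, adjusted p = 0.465 with an estimated correlation). Elastic fibre genes fell in 9 of 18 and rose in 2 (9 and 2 adjusted over the list alone, median −1.61, limma camera adjusted p = 0.0423, adjusted p = 0.459 with an estimated correlation), a call that ended without animal 6 (adjusted p from 0.000760 to 0.0880 over the alternatives). Stress-response genes rose in 23 of 46 and fell in 2 (26 and 4 adjusted over the list alone, median 0.59, limma camera adjusted p = 9.03e-05, adjusted p = 0.598 with an estimated correlation). Yet FOS, chosen after its values were seen, was 231 against 464 CPM. Against cartilage-like and fibrous-like cells only, 5423 genes differed (3906 shared). The calls of the stress, progenitor-associated and IGF and FGF lists ended there (medians −0.17, 0.31 and 0.00), at the top of limma camera ranges over the alternatives of 3.92e-10 to 0.999, 0.00499 to 0.0685 and 0.00887 to 0.524. Oxidative phosphorylation was called only there, and protease inhibitors there and without animal 8 (limma camera adjusted p from 0.00892 to 0.913 and from 0.00177 to 0.162 over the alternatives). The oxidative phosphorylation median was 0.26 there (25 rose and 7 fell of 68). The median mitochondrial share was higher too, at 2.39, 2.48 and 2.96% in mural-like cells of animals 6, 7 and 8. It was 0.663, 0.626 and 0.605% in cartilage-like and 1.03, 0.896 and 1.61% in fibrous-like cells. Mural markers rose in 11 of 12 (median 6.06, limma adjusted p = 0.0264 with an estimated correlation), as the naming of the class by them required. Notochordal (7 of 13), cartilage-like (10 of 14) and keratinocyte markers (4 of 5) fell, with adjusted p = 0.467, 0.427 and 0.427 with an estimated correlation. Of the 40 lists of these 2 classes camera called 16, with an estimated correlation 0, and 11 against cartilage-like and fibrous-like cells only.

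Cartilage-like cells of animals 6 and 8 were divided differently over clusters. Cluster 5 held 51.9 and 56.8% of the class in animal 6 and 38.3 and 9.40% in animal 8, and cluster 8 held 19.2 and 9.99% against 39.6 and 57.1%. Values within the class follow this makeup too, and ULBP21 was among the 10 leading genes of a cartilage-like cluster of 562 cells at resolution 1.2. Between these animals, cartilage-like cells differed in no gene by edgeR, although genes among those with the smallest p, chosen after their values were seen, lay far apart. ULBP21 was 169 ± 25.9 CPM in animal 6 and 2.99 ± 1.78 in animal 8 (mean ± SD, 2 discs each; log2 difference 5.81 ± 0.439; edgeR adjusted p = 0.0583), and 3.09 in animal 7. CRYAB was 3941 against 831 CPM and COCH 80.2 against 1.57 CPM. DCN was 2801 against 8546 CPM, COMP 6065 against 14955, GPX3 356 against 1225 and RFC3 28.1 against 135 CPM. Of 12909 genes edgeR called 0 and 3487 had an unadjusted p under 0.05. RLE scaling gave 0 as well, DESeq2 1071 (557 higher in animal 6) and edgeR without a count filter 1602. Without animal 6 disc 3 or disc 4 edgeR called 8 or 5 genes, without the disc of animal 7 0, without animal 8 disc 2 461 and without animal 8 disc 1 4651. A side with 1 disc is assumed to vary like the other animals. These p measure only the spread between discs of 1 animal, and 1 animal stood on each side.

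Cartilage-like profiles of discs 3 and 4 of animal 6 correlated at 0.991 (Pearson, log2 CPM, 12909 genes), the highest of all pairs, but discs 1 and 2 of animal 8 only at 0.969. Both were closer to the disc of animal 7, disc 1 at 0.982 and disc 2 at 0.986. In sums over all kept cells disc 2 was again closer to animal 7 (0.989) than to disc 1 (0.974), but disc 1 was not (0.967). Within-animal correlations averaged 0.980 and between-animal ones 0.967, a difference of 0.0136 (exact permutation p = 0.267, one-sided, 4 of 15 splits). The smallest p possible was 0.0667. Grouping animal 8 disc 2 with animal 7 gave 0.0242, the largest of the 15 splits. This grouping was chosen after the same correlations were seen, so its rank cannot decide on the label.

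**Figure D4:**
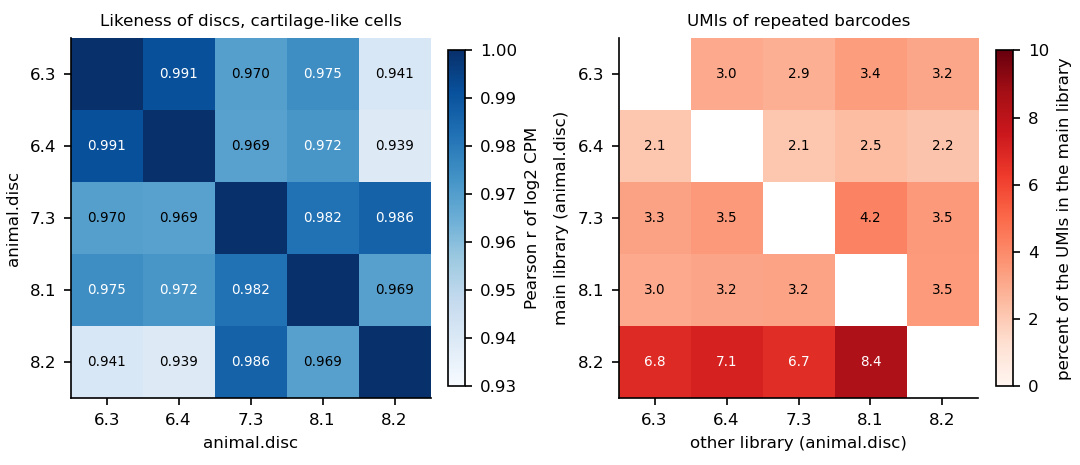
Pearson correlation between discs in cartilage-like cells, and UMIs of repeated barcodes as a percent of those in the library with the most.

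Cartilage-like cells of the disc without dead cell cleanup were set beside those of the other disc of animal 8, with intervals that cover counting error only. Cluster 6, led by HP, held 9.10 against 2.65% of the class, cluster 5 9.40 against 38.3% and cluster 8 57.1 against 39.6%, so values within the class also follow this makeup. HP was 216 CPM (exact Poisson 95% interval 207 to 225) against 20.2, a ratio of 10.7 (9.40 to 12.2). LAMB1 was 8.95-fold higher (6.51 to 12.6), MANSC1 8.20-fold (4.92 to 14.5), M-SAA3.2 5.94-fold (4.81 to 7.39), NDP 5.64-fold (4.66 to 6.86) and C1QTNF7 4.97-fold (4.30 to 5.78). LORICRIN, with 2 against 1096 counts, was 491-fold lower (136 to 4061), SERPINF1 (2 against 169) 75.7-fold (20.6 to 631) and H2BC13 (2 against 141) 63.2-fold (17.2 to 527). The 2 genes with the symbol CALCB were 25.7-fold (18.8 to 36.2) and 19.5-fold (11.7 to 35.3) lower. COL1A2 was 20.6-fold lower (18.6 to 22.9; 32.8 against 677 CPM), in a disc with fewer fibrous-like cells (24.6 against 36.0%). With the looser cell filter M-SAA3.2 reached 50.1-fold (31.9 to 83.6) and NDP 7.00-fold.

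Of 8303 genes, 5739 lay outside the range of the other 4 discs (3400 higher, 2339 lower). Among 11189 genes this disc lay outside the range of the others for 67.4%, against 17.9 to 43.7% for each other disc. A gene can have only 1 highest and 1 lowest disc, so a high share in this disc lowers the others. The other discs are therefore no independent reference, and many genes lie outside the range in any disc. Cleanup, disc position and the likeness to animal 7 cannot be told apart with 1 library.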

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

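The tests of the causes weighed in this part were all chosen only after the result was seen. Of 14 measures compared over the 5 discs, Dixon's ratio passed its critical value of 0.71 for 2, both in disc 1 of animal 8. Its median mitochondrial share was 1.32% (gap over range 0.717), with the other discs at 0.701 to 0.876%. Cartilage-like cells were 21.5% of its cells (0.790), with the other discs at 45.6 to 52.0%. Chance alone passes the value in about 1 of 20 groups of values.

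The notochordal-like cluster held 9 cells of animal 8, with a median of 1056 UMIs. Only 1 kept cell of that animal held at least 3 of KRT8, KRT18, KRT19, TBXT, SHH and CDH2. That cell was itself a repeat, as were all removed barcodes of animal 8 with at least 3 of these genes. All 9 had more UMIs in the disc of animal 7, which is consistent with reads carried between libraries that share a barcode. Against chance repeats of a sequence, 100% of 300 sampled repeats were closer to the cell with their own barcode than to another cell of that library (median r across genes 0.595 against 0.408). Repeats held 2.12 to 8.42% of the UMIs at their source as medians per pair of libraries. The step that carried the reads, and whether animal 8 holds notochordal-like cells at all, stays open.

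Animal 8 disc 2 was closer to the disc of animal 7 than to disc 1 of animal 8 in cartilage-like cells (0.986 against 0.969, with or without repeated barcodes), and their removal moved these values too little to decide on carried reads as the cause; disc 1 was closer to animal 7 as well (0.982), though not in sums over all kept cells (0.967 against 0.974), so the likeness in this class is not particular to disc 2. Single clusters were closer to animal 7 in 9 of 10 cases, which argues against a different cluster makeup, although mural-like cells went the other way (0.886 against 0.916). Genes that differed alike in 4 classes numbered 7 between the discs labelled animal 8 and 1 between disc 2 and animal 7, a difference consistent with a mislabelled sample, while the discs of animal 6 gave 0 and pairs of different animals other than this one 5 to 28. Genes named below differed between the discs labelled animal 8 and between animal 7 and disc 1, but not between animal 7 and disc 2. This rule fixed their likeness in the last pair beforehand. ENSBTAG00000032057 was 17.0 to 26.2 CPM in animal 7 and 14.6 to 22.1 in animal 8 disc 2, and at most 1.02 elsewhere. ENSBTAG00000019018 was at most 1.42 and 4.47 CPM there and 3.26 or more elsewhere. ENSBTAG00000006383 and ENSBTAG00000040518 were high in animal 8 disc 1 alone (36.1 to 38.4 and 4.89 to 44.4 CPM). They were at most 10.7 and 3.92 CPM elsewhere, so they set disc 1 apart from animal 6 too. The files do not pair these with names. The counts are small, discs 1 and 2 differ in cleanup and position, and genotypes were not analysed here, so the animal of this disc stays open, as does any part of carried reads.

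Stress-response genes such as FOS, JUN, HSPA1A and ZFP36L1 were high in fibrous-like cells, mainly through cluster 9, although in animal 8 disc 1 the median share of UMIs from the whole list was 2.09% in fibrous-like and 2.61% in cartilage-like cells, the opposite of the other 4 discs. Cells of cluster 9 at or above the median depth of their disc held 10.8% of UMIs from this list, against 1.74% in cluster 3, which argues against shallow cells as the cause. Without cluster 9 the list median dropped from 2.10 to 0.24. A response to digestion and overnight handling is a candidate explanation, and so is a state of these cells in the tissue. No undigested tissue was analysed here, so the 2 could not be told apart.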

How the results depend on the processing

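Leaving the animal out of the model (no replicate block) gave 4559 genes between fibrous-like and cartilage-like cells (5394 with the block), 4459 between notochordal-like and cartilage-like cells (5049), 4916 between notochordal-like and fibrous-like cells (5322), 36 of 60 disc lists and 15 of 40 others. Among lists it ended the calls of glycosaminoglycan synthesis in fibrous-like against cartilage-like cells, of WNT, Hedgehog and Notch in notochordal-like against fibrous-like cells and of elastic fibre genes in endothelial-like cells, and added elastic fibre and complement genes in notochordal-like against cartilage-like cells. It changed no other call. Sums thinned to the same total gave 2447 and 3225 of 8590 genes for the first pair of comparisons, and a log2 fold change of at least 1 gave 3219 for fibrous-like cells. Over animals and discs left out the counts were 3407 (without animal 8) to 5029, 2532 (without animal 6) to 5022, and 2882 (without animal 6) to 5159. With an estimated correlation camera called 0 of 60 and 0 of 40 lists. Between animals 6 and 8 DESeq2 called 1071 genes, edgeR without a count filter 1602, sums over all kept cells 1, and discs left out 0 (animal 7) to 4651 (animal 8 disc 1).

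The stricter filter kept 14689 cells, the looser one 25503, and removal of repeated barcodes 15701. Cartilage-like cells were 60.9% under the stricter filter and 54.9% with doublets kept. Notochordal-like cells were 0% with values centred over all cells. Unnamed cells were 9.13% at resolution 0.4, 0.711% under the stricter and 26.7% under the looser filter, 9.50% with doublets kept, 9.46% with the highest doublet scores removed, 11.9% with values centred over all cells and 12.1% with repeats removed. Among alternatives for counts, shares and likeness 167 stayed within 1.5-fold or, for shares, within 1 SD, with the 3 other cell totals above all counted as changed, and 34 did not. For gene lists, retested in fewer settings, 822 kept the call or its absence, 88 weakened and 30 became stronger. For named genes 2343 kept the call and 34 weakened, with none reversed. For all results that changed, the cause was not tested.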

Other observations

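Cells with lubricin and acute-phase transcripts lay outside the named classes in the main clustering and at resolution 1.2. A similar cluster was named cartilage-like under the stricter and looser filters, with doublets kept, with the highest doublet scores removed and with values centred over all cells (scores of 0.973 to 1.69), and merged with other cells at resolution 0.4. Cluster 2 (1288 cells) was led by PRG4, which encodes lubricin, with SAA3, HP and SOD2, at a median of 8090.5 UMIs, so that low depth did not set it apart. It held 12.5% of the cells of animal 7 and 12.9% of animal 8 disc 2, against 3.94 to 6.60% of the other discs. Cluster 13, with TYROBP, FCER1G and IL7R, made up 1.63% of animal 8 disc 1 and at most 0.347% of each other disc, and its myeloid, mast and lymphoid scores were 5.10, 4.85 and 4.68. The stricter filter gave a myeloid-like cluster of 37 cells and a mast-like cluster of 48 cells.

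Chaperone-rich cartilage-like cells formed cluster 8 (2107 cells), where HSPA5, SDF2L1, HERPUD1 and DNAJB11, chaperones and stress genes of the endoplasmic reticulum, led at a median of 15313 UMIs. They were 24.2% of the cells of animal 7 and 26.0% of animal 8 disc 2, against 4.65 to 9.74% of the other discs. Within the cartilage-like class, disc 1 of animal 8 was not set apart from these. There cluster 8 held 46.5% in animal 7 and 39.6 and 57.1% in discs 1 and 2 of animal 8. In discs 3 and 4 of animal 6 it held 19.2 and 9.99%. Schwann-like cells held NES, chosen after its value was seen, at 1306 CPM and SOX10 at 415 CPM, in 1 sum of 33 cells from animal 6.

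The tests on regrouped sums in this part were chosen only after the result was seen. Between fibrous-like and cartilage-like cells, 4123 of 12474 genes differed when only these 6 sums were fitted, and the highest count in any other of the 10 splits was 0. With 10 splits in all, there were too few to judge this result. For endothelial-like cells against the disc classes, 2594 of 12068 genes differed and the highest of the other splits gave 9, with 1 of 40 drawn from 165 as large. For mural-like cells 801 of 11737 genes differed and the highest other gave 1, again 1 of 40. The classes came from clustering these cells, so sums grouped by class must differ more than regrouped sums, and the splits cannot decide on chance.

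The difference between fibrous-like and cartilage-like cells was also compared between animals 6 and 8. This fit used sums per disc and did not pair the classes of a disc. Its spread was that between discs of the same animal, animal 8 disc 2 included. Of 13197 genes edgeR called 0 for this interaction, and 901 had an unadjusted p under 0.05. The 0 calls therefore do not show that the animals are alike. Across 5579 genes, deviations from the class mean correlated between pairs of 4 classes at 0.0127 to 0.507 within an animal and at −0.382 to 0.181 between animals. For cartilage-like and fibrous-like cells they were 0.283 in animal 6, 0.360 in animal 8 and 0.0127 in animal 7, below the 0.0946 of a pair from different animals. Centring ties the 2 sets of values together, so neither is an independent reference.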
